A study of Mus musculus with 20 samples.

How the data were processed

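The series measured total RNA from the hippocampus of 20 male C57BL/6 mice in 4 groups of 5, libraries being made with the TruSeq RNA kit v2 per the labels' protocols. Per the submitters' processing notes, the genome build was GRCm38 and the tools named were bcl2fastq 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4; the annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. Where near-identical genes exist, as among the beta protocadherins and the class I genes of antigen presentation, the division of reads between copies is therefore uncertain, and so is that between overlapping or antisense genes.

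The authors deposited a table of raw read counts per Ensembl gene for all 20 libraries, with 47729 gene rows, and a table of values they named RPKM. Symbols were taken from a gene name table for 47224 rows and from GENCODE M21 for 86; 419 rows, holding 0.0492% of counts, had no symbol and kept their identifiers. Coordinates are those of GENCODE M21 on GRCm38. Chi-square values per degree of freedom between libraries of a group ran from 7.05 to 67.1, so no 2 libraries of the same group agreed within sampling noise. The deposited RPKM values were not depth-normalised per library: the ratio of count to RPKM cycled down the gene rows with a period of 40, and column sums, from 189901 to 377500, followed the count totals. They entered 1 alternative only. Each title carries its own number, read here as that of the animal. Nothing else in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries. Replicate numbers only name libraries and pair nothing.

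Counts were analysed with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter on the 4 groups, a robust quasi-likelihood fit of the group means over all 20 libraries without covariates, and Benjamini-Hochberg adjustment with a threshold of 0.05. Contrasts were treadmill against control at each age, their difference and average, and 20 against 5 months in control and in treadmill mice. Fold changes are log2 with their SE, intervals cover 95%, and values are CPM, mean ± SD. Adjusted p-values of genes come from this test unless another tool is named. These choices, the gene lists and the naming rule were made before the data were examined.

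Gene lists, 41 in number, covered cell types, adjoining tissue, immune, stress and metabolic pathways. Each was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated one, adjusted over the lists, and per library by a score, the mean over members of log2 CPM (prior count 2) centred per gene. Scores were compared by two-sided exact permutation over the 252 assignments of 5 and 5, whose smallest p is 0.00794. Named genes were, among called genes with a mean of at least 1 CPM and without clone or predicted names, the 10 highest and 10 lowest fold changes (5 and 5 for age in treadmill mice and the average treadmill effect); up to 4 called members per list by p; the 5 smallest p where fewer than 5 genes were called; and a panel of 19 genes.

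Alternatives were median-of-ratios and upper-quartile factors, no filter beyond 1 count, a filter on a mean of 1 CPM, DESeq2 1.42.0, limma-trend on log2(RPKM + 0.1), only the libraries compared, 1 surrogate variable (sva 3.50.0), the choroid plexus score as a covariate, fry, and leaving out each library. Added after seeing the data were the removal of 5 libraries with a choroid plexus score above 2, offsets per library in 20 bins of transcript GC content, and the average age effect over both treadmill groups with the agreement of the age changes.

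The test was tried on simulated counts with 200 changed genes, all drawn from genes with a mean of at least 1 CPM. These were changed 1.5-, 2- or 4-fold, 67 of them 1.5-fold, in 1 simulated data set per contrast. Counts were drawn independently for each gene, without the shared differences between libraries, so recovery in the real libraries may be lower. With many changed genes the adjusted threshold is also easier to pass. The percentages therefore do not give the recovery of a few changed genes. Of genes changed 1.5-fold, 76.1% were recovered for treadmill at 5 months (16786 genes tested), 70.1% for treadmill at 20 months (16813), 47.8% for the interaction (16795), 86.6% for the average treadmill effect (16784), 79.1% for age in control mice (16785) and 62.7% for age in treadmill mice (16806). Of genes changed 2-fold, 92.5%, 89.6%, 71.6%, 98.5%, 94.0% and 95.5% were recovered in the same order.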

Results

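RNA sequencing of the hippocampus was analysed in 20 male C57BL/6 mice. Mice of 5 and of 20 months were either controls or exercised on a treadmill, which gave 4 groups of 5 libraries. Each library was taken to come from its own animal, by the number in its title. The titles of the older animals carry the number 24, while their age label reads 20 months. The age label was used throughout. Total counts per library ran from 17653438 to 34495780. Their means were 21924183 (SD 3208206, n = 5) in 5-month controls and 24732638 (SD 7491184) in 5-month treadmill mice. At 20 months they were 27526902 (SD 2307376) in controls and 23691534 (SD 2934831) in treadmill mice. The 20-month controls were sequenced more deeply than the 5-month controls (two-sided exact permutation test, p = 0.0238). In all, 16945 genes passed the filter on low counts.

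Markers of the choroid plexus, the secretory epithelium of the brain ventricles that adjoins the hippocampus, stood far apart in 5 libraries. Their choroid plexus scores were 4.21 and 3.10 in replicates 3 and 4 of the 5-month treadmill group, 3.53 in replicate 1 of the 5-month controls, 3.64 in replicate 1 of the 20-month treadmill group and 3.68 in replicate 1 of the 20-month controls. The other 15 libraries lay at or below -0.249. Transthyretin (Ttr), the main secreted protein of this epithelium, reached 3198 to 6826 CPM in the 5 libraries and 4.96 to 137 CPM in the others. Folr1, a folate receptor, ranged from 26.4 to 58.2 CPM against 0.214 to 1.76 CPM, and Aqp1, a water channel, from 16.6 to 45.7 CPM against 0.261 to 1.29 CPM. The first principal component held 30.6% of the variance of log2 CPM over libraries. Each group held at least 1 of the 5 libraries, so each comparison was also run without them.

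**Figure D1:**
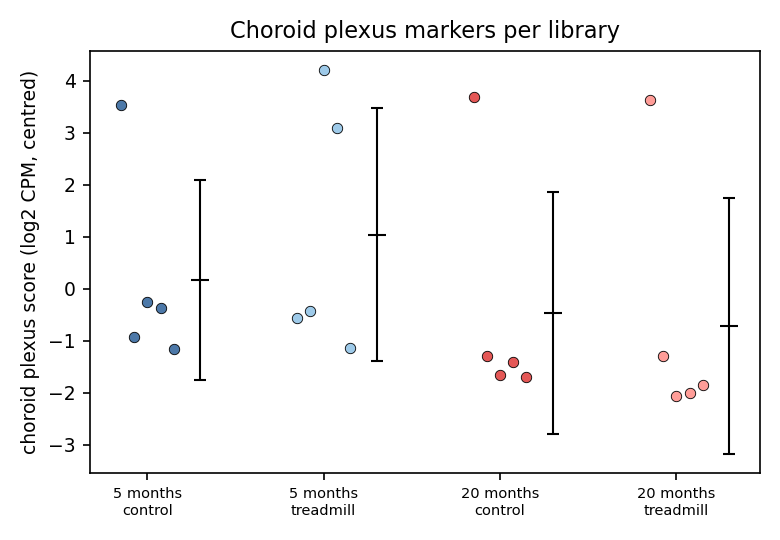
Score of the choroid plexus markers (mean centred log2 CPM over 18 genes, y axis) in each library of the 4 groups (x axis); points are libraries, and bars are the group mean and SD (n = 5). In total 5 libraries lay above 2, and the other 15 lay at or below -0.249.

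Whether treadmill exercise changed the hippocampal transcriptome of young adults was examined at 5 months. No gene passed the threshold in edgeR's quasi-likelihood test, with 295 of 16945 genes at an unadjusted p under 0.05, where chance gives 847.2 on average. DESeq2 also called 0 genes, with 230 at that unadjusted p. On the deposited RPKM, which were not depth-normalised, limma called 0 genes, with 141 at that p. The log2 ratio of count to RPKM varied around the gene mean with an SD of 0.333, so this 0 adds little. Among factors linked to exercise, the neurotrophin Bdnf measured 49.0 ± 6.90 CPM in treadmill mice and 43.7 ± 3.33 CPM in controls (SD, n = 5 each), a log2 fold change of 0.16 with a 95% interval from -0.10 to 0.43. Bdnf reached 61.2 CPM in replicate 5 of the treadmill group, against 44.9 to 47.7 CPM in the other treadmill libraries. Its receptor Ntrk2 differed by 0.00 on the log2 scale (interval -0.12 to 0.12), the growth factor Igf1 by 0.02 (interval -0.15 to 0.18), the angiogenic factor Vegfa by 0.10 (interval -0.06 to 0.27) and Ppargc1a, a regulator of mitochondrial genes, by -0.03 (interval -0.18 to 0.11). The activity-induced genes Fos, Arc, Egr1 and Npas4 had log2 fold changes of -0.03, -0.02, 0.03 and -0.00, and Dcx, a marker of immature neurons, of -0.14 (interval -0.46 to 0.17). The smallest p-values belonged to Rmrp, the RNA of an RNA-processing endonuclease, with a log2 fold change of 3.02 (SE 0.72), to Gm5814 (-0.76, SE 0.18), to 2810049E08Rik (1.51, SE 0.40), to Ccdc188 (0.96, SE 0.25) and to Gm25395 (1.92, SE 0.54); none passed the threshold (adjusted p = 0.99995 each).

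Of the 41 gene lists, 19 were called at 5 months with camera's preset correlation, 15 of them higher and 4 lower, and 1 with an estimated correlation. The lymphocyte list kept its call: 4 of its 5 measured members (Lck, Cd79b, Jchain, Ighm and Igkc) had a positive log2 fold change, with a median of 0.57, and the adjusted p was 0.000325, and 0.0303 with an estimated correlation. Its score was higher by 0.579 in treadmill mice (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 can give; adjusted p = 0.325 over the 41 lists). All 5 members of the erythrocyte list, among them the haemoglobin genes Hba-a1 and Hbb-bs, were positive with a median of 0.94 (adjusted p = 5.75e-10, and adjusted p = 0.131 with an estimated correlation). Of these, 2 were called when adjusted over the list alone and 0 over all genes. Replication-dependent histones were positive in 8 of 9 members with a median of 0.28 (adjusted p = 6.25e-07, and adjusted p = 0.363 with an estimated correlation), but in the list score replicate 2 of the treadmill group stood apart at 0.932, the other 4 lying between 0.0442 and 0.250. Oligodendrocyte and myelin genes were negative in 17 of 18 members with a median of -0.10 (adjusted p = 0.00191, and adjusted p = 0.682 with an estimated correlation). All 18 choroid plexus markers were positive with a median of 1.03 (adjusted p = 0.00533, and adjusted p = 0.705 with an estimated correlation), and 2 of the 5 libraries high in these markers were in the treadmill group. Neither the neurotrophic and exercise-linked factors (median 0.00, adjusted p = 0.323) nor adult neurogenesis (median -0.08, adjusted p = 0.232) nor immediate early genes (median -0.00, adjusted p = 0.852) were called. Without the 5 libraries high in choroid plexus markers, edgeR also called 0 genes, but 1485 of 17219 had an unadjusted p under 0.05. With all libraries 295 of 16945 did, where chance gives 847.2 on average. Counts vary widely around that average: other splits of the 5-month libraries, with none removed, gave 200 to 2534 genes at that p. The 1485 lay within that range, so it does not stand apart from chance. The cause of the move was not tested.

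The same question was put to the aged hippocampus at 20 months. No gene passed the threshold in edgeR's test, with 309 of 16945 genes at an unadjusted p under 0.05, and DESeq2 called 0 genes with 277 at that p. On the deposited RPKM limma called 0 with 263, which adds little because those values were not depth-normalised. Bdnf measured 44.7 ± 8.63 CPM in treadmill mice and 46.4 ± 7.70 CPM in controls (SD, n = 5 each; log2 fold change -0.05, 95% interval -0.32 to 0.21). The log2 fold changes were -0.03 for Ntrk2, -0.03 for Igf1, -0.02 for Vegfa, 0.09 for Ppargc1a and 0.20 for the secreted neuropeptide precursor Vgf. Npas4, a transcription factor induced by neuronal activity, measured 10.1 ± 3.41 against 7.06 ± 1.87 CPM, a log2 fold change of 0.52 (interval 0.11 to 0.92, adjusted p = 0.99985), and Fos, Arc and Egr1 had values of 0.27, 0.29 and 0.17. The glial and immune markers Gfap, Aif1, Cd68 and C4b had log2 fold changes of -0.03, -0.06, 0.06 and 0.09. The smallest p-values belonged to Nme9 (-1.75, SE 0.36), the dynein heavy chain gene Dnah3 (-0.97, SE 0.23), Frmpd2 (-1.08, SE 0.26), Stmnd1 (-1.67, SE 0.43) and Gm44109 (-1.90, SE 0.49), none of which passed the threshold (adjusted p = 0.99985 each).

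Of the 41 lists, 18 were called at 20 months with the preset correlation, 12 higher and 6 lower, and 0 with an estimated correlation. All 10 ependymal markers, genes of the ciliated cells that line the ventricles, were negative with a median of -0.58 (adjusted p = 3.29e-09, and adjusted p = 0.321 with an estimated correlation), and 1 was called when adjusted over the list alone. The score difference, treadmill minus control, was -0.665, within the spread of the libraries (two-sided exact permutation p = 0.159, adjusted p = 0.984). Replicate 1 of the controls, a library high in choroid plexus markers, had the highest score, 1.24. Immediate early genes were positive in 23 of 27 members with a median of 0.17 (adjusted p = 8.62e-07, and adjusted p = 0.321 with an estimated correlation), and 1 was called when adjusted over the list alone. Genes of the unfolded protein and integrated stress response were positive in 15 of 17 members with a median of 0.12 (adjusted p = 2.63e-05, and adjusted p = 0.321 with an estimated correlation). Markers of CA1 pyramidal neurons were positive in 8 of 8 members with a median of 0.13, and those of CA2 and CA3 were negative in 9 of 9 with a median of -0.12. The adjusted p were 0.000689 and 0.00670, and with an estimated correlation the adjusted p was 0.321 for each. Oligodendrocyte and myelin genes were negative in 17 of 18 members with a median of -0.13 (adjusted p = 0.00162, and adjusted p = 0.761 with an estimated correlation).

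**Figure D2:**
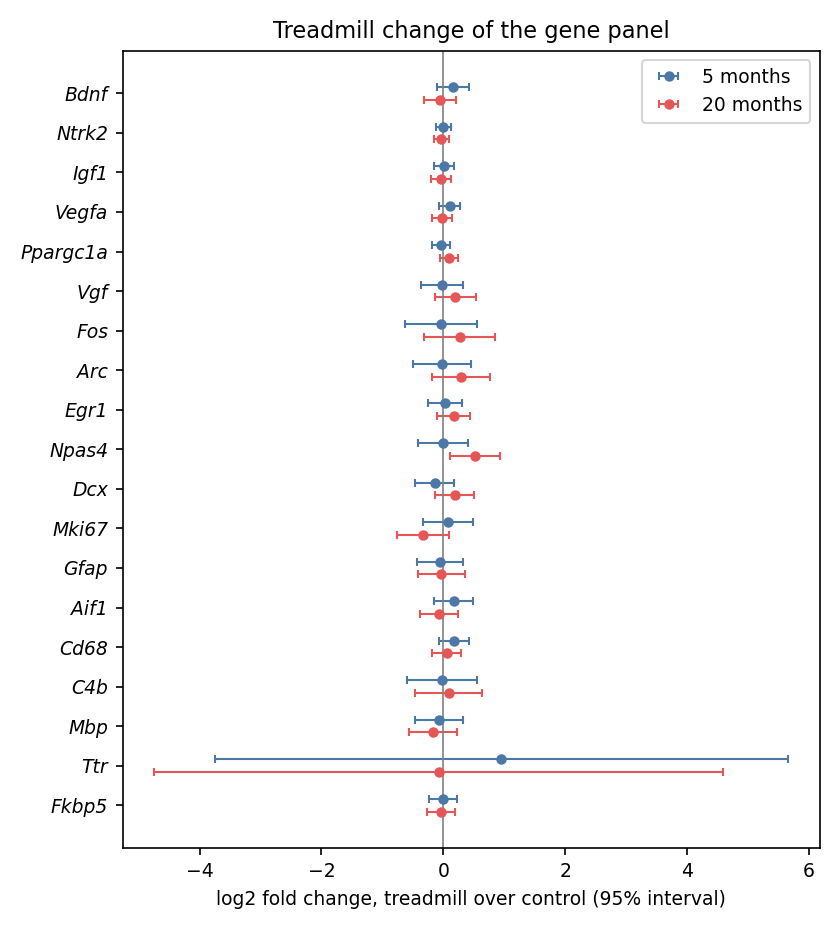
Treadmill over control log2 fold change (x axis) with its 95% interval for each gene of the panel (y axis), at 5 months in blue and at 20 months in red (n = 5 per group). Of the 20-month intervals shown, that of Npas4, from 0.11 to 0.92, lay above 0; none of these genes passed the threshold after adjustment.

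A difference of the treadmill change between ages, and its average over both ages, were tested in the same fit. For the interaction, edgeR called 0 genes, with 328 at an unadjusted p under 0.05, and DESeq2 and limma called 0 with 302 and 300. For the average, edgeR called 0 genes, with 274 at that p, and DESeq2 and limma called 0 with 209 and 88. In both cases limma used the deposited RPKM, which were not depth-normalised, so its counts add little. The smallest p for the interaction belonged to the cadherin gene Cdh6 (0.65, SE 0.17), to Pold2, a subunit of DNA polymerase delta (0.30, SE 0.08), to Mfap1b (-0.55, SE 0.16), to Meig1 (-0.85, SE 0.24) and to the potassium channel subunit gene Kcne4 (1.10, SE 0.32), and none passed the threshold. For the average they belonged to Dnah3 (-0.64, SE 0.16), Frmpd2 (-0.72, SE 0.18), BC051019 (-1.02, SE 0.26), Nme9 (-0.91, SE 0.24) and the collagen gene Col6a5 (-0.53, SE 0.14), again short of it. With the preset correlation 20 lists were called for the interaction and 14 for the average, and 0 in either with an estimated correlation. Oligodendrocyte and myelin genes were negative on average in 18 of 18 members with a median of -0.12 (adjusted p = 8.36e-07, and adjusted p = 0.626 with an estimated correlation). Endothelial markers were positive in 15 of 16 and mural markers in 11 of 11, with medians of 0.11 and 0.16 (adjusted p = 1.48e-05 and 1.50e-05, and adjusted p = 0.594 for each with an estimated correlation). Across the 16945 genes, the changes at 5 and at 20 months had a Pearson correlation of -0.0893 and a Spearman correlation of -0.138. The Pearson correlation turned positive without replicate 3 of the 20-month treadmill group (0.0130) or replicate 1 of the 20-month controls (0.0401). Genes are not independent replicates, and exact permutation of the libraries within each age gave p = 0.653 and p = 0.424 over 63504 assignments. The 95% interval of the treadmill change lay within 1.5-fold either way for 90.3% of 14446 genes with a mean of at least 1 CPM at 5 months, 91.0% at 20 months and 96.8% for the average.

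What ageing changes in the hippocampus was first examined in control mice. At 20 months 12 genes were higher and 0 lower than at 5 months, and 1293 had an unadjusted p under 0.05. Clustered beta protocadherins, neuronal cell-surface adhesion proteins encoded side by side on chromosome 18, made up 4 of the 12. Pcdhb9 rose from 14.8 ± 0.639 to 23.1 ± 2.78 CPM (log2 fold change 0.64, SE 0.08, adjusted p = 0.000776). Pcdhb2 rose from 3.50 ± 0.634 to 6.27 ± 0.874 CPM (0.84, SE 0.14), Pcdhb6 from 3.02 ± 0.275 to 5.59 ± 1.09 CPM (0.89, SE 0.16) and Pcdhb1 from 0.236 ± 0.0591 to 0.739 ± 0.169 CPM (1.62, SE 0.25). Of the 22 measured members 9 were called when adjusted over the list alone, and the list was higher (median 0.26, adjusted p = 6.12e-16, and adjusted p = 0.0174 with an estimated correlation). H2-D1, a heavy chain of class I antigen presentation at chromosome 17, 35262730 to 35267499 on GRCm38, rose from 27.4 ± 4.91 to 42.9 ± 4.51 CPM (0.64, SE 0.11, adjusted p = 0.00884). Spag6, a gene of the ciliary axoneme at chromosome 2, 18694032 to 18750413, rose from 2.85 ± 0.192 to 5.69 ± 0.697 CPM (0.999, SE 0.11, adjusted p = 9.48e-05). Upk1b, a tetraspanin of the urothelium, rose from 1.79 ± 0.486 to 3.54 ± 0.234 CPM (0.99, SE 0.15), and Zc3hav1, an antiviral zinc finger protein, from 9.81 ± 1.24 to 14.3 ± 1.36 CPM (0.55, SE 0.09).

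Several immune lists were higher in aged controls by camera. By exact permutation of the list scores, 0 of 41 lists passed the threshold after adjustment (smallest adjusted p = 0.145). Antigen presentation genes were positive in 18 of 19 members with a median of 0.62 (adjusted p = 1.88e-18, and adjusted p = 0.0174 with an estimated correlation). Of these, 1 was called over all genes and 10 when adjusted over the list alone. Markers of disease-associated microglia were positive in 18 of 20 with a median of 0.35 (adjusted p = 6.13e-15, and adjusted p = 0.0174 with an estimated correlation), 0 called over all genes and 11 when adjusted over the list alone. Among them Cd68, a lysosomal protein of phagocytes, measured 10.3 ± 0.638 against 7.23 ± 0.623 CPM (0.52, SE 0.12, adjusted p = 0.136). Complement genes were positive in 13 of 15 with a median of 0.40 (adjusted p = 2.18e-09, and adjusted p = 0.0393 with an estimated correlation), with 7 called when adjusted over the list alone. C4b measured 85.4 ± 29.1 against 31.5 ± 3.76 CPM (1.44, SE 0.27, adjusted p = 0.0740). The lymphocyte list was higher too (median 0.63, adjusted p = 0.000829, and adjusted p = 0.0174 with an estimated correlation), but not in treadmill mice (median 0.01, adjusted p = 0.838). Its mean score was -0.447 in the 5-month controls, the low group, against 0.132 in the 5-month treadmill group, 0.307 in the 20-month controls and 0.008 in the 20-month treadmill group. The rise with age in controls and the treadmill rise at 5 months thus shared the same 5 low libraries. The erythrocyte score also rose in controls, from -0.474 to 0.1, a difference within the spread of the libraries (two-sided exact permutation p = 0.262). Interferon-stimulated genes were positive in 22 of 24 with a median of 0.42 (adjusted p = 1.03e-09), and homeostatic microglia in 15 of 16 with a median of 0.20 (adjusted p = 6.19e-10), but with an estimated correlation the adjusted p were 0.262 and 0.172. Adult neurogenesis genes were negative in 14 of 18 members with a median of -0.09 (adjusted p = 7.80e-05, and adjusted p = 0.0174 with an estimated correlation), and 4 were called when adjusted over the list alone. Dcx measured 21.1 ± 3.43 against 24.3 ± 4.68 CPM (-0.21, adjusted p = 0.790). Cell cycle genes were negative in 15 of 22 with a median of -0.06 (adjusted p = 0.00274, and adjusted p = 0.0174 with an estimated correlation). Heat shock genes were negative in 13 of 14 with a median of -0.13 (adjusted p = 7.80e-05, and adjusted p = 0.172 with an estimated correlation). With only the 10 control libraries in the fit 4 genes were called, DESeq2 called 44 and limma on the deposited RPKM 1. Without the 5 libraries high in choroid plexus markers 8 were called.

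**Figure D3:**
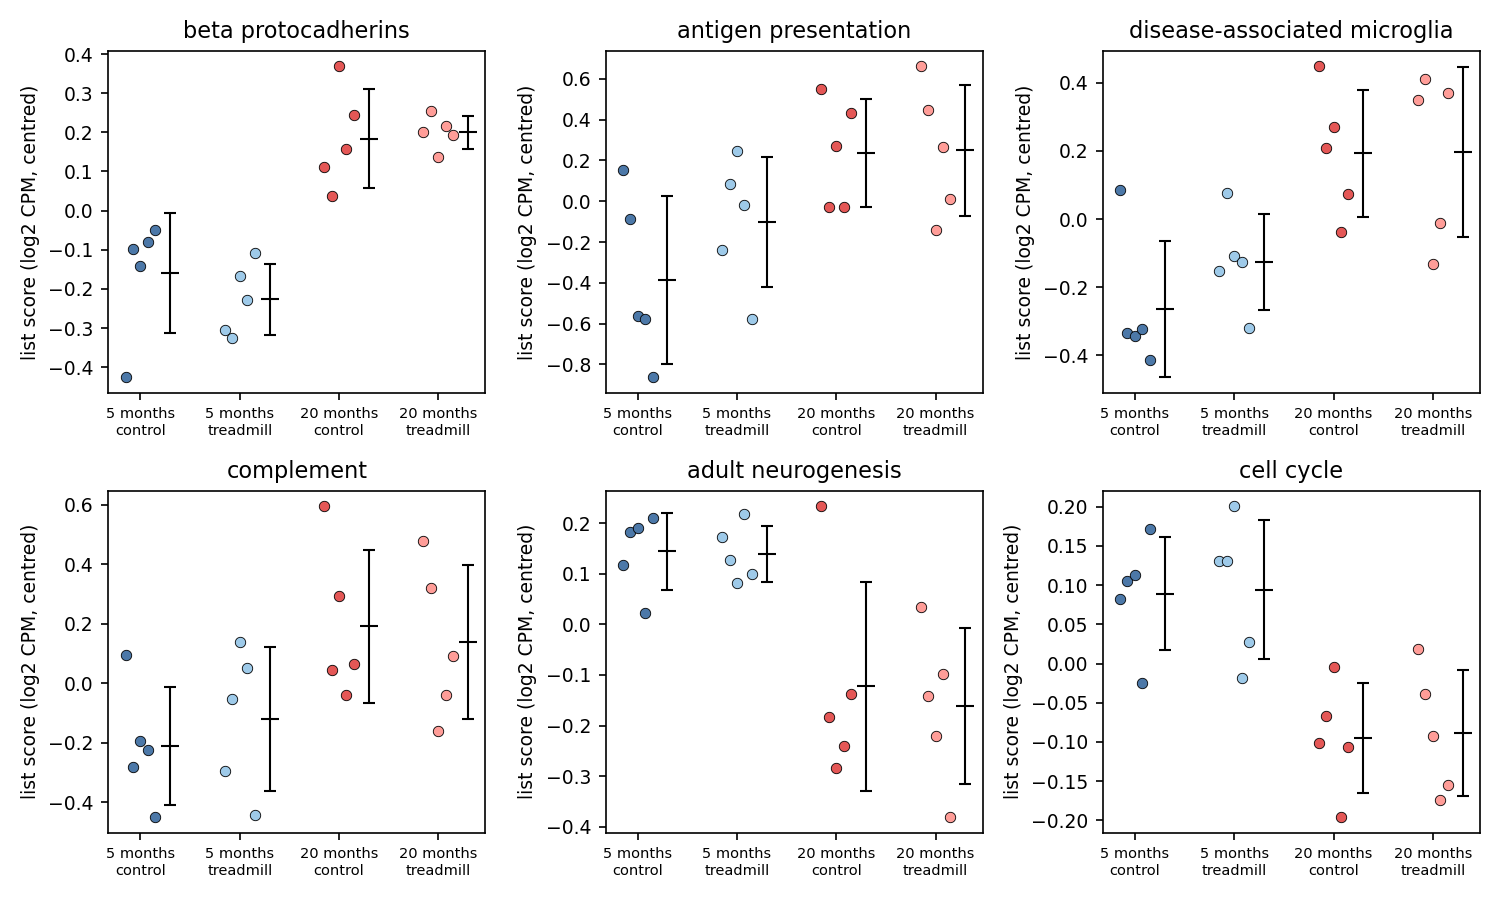
List score (mean centred log2 CPM, y axis) of 6 gene lists in each library of the 4 groups (x axis); points are libraries, and bars are the group mean and SD (n = 5). The beta protocadherin score was higher at 20 than at 5 months by 0.342 in controls and 0.427 in treadmill mice, and the adult neurogenesis score was lower, with differences of -0.267 and -0.301.

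In treadmill mice the same age comparison called 65 genes, 57 higher and 8 lower at 20 months, with 2113 at an unadjusted p under 0.05. By exact permutation of the list scores, 0 of 41 lists passed the threshold after adjustment (smallest adjusted p = 0.0813). Of the 22 beta protocadherins 7 were called over all genes and 13 when adjusted over the list alone (median 0.35, adjusted p = 1.35e-19, and adjusted p = 0.0334 with an estimated correlation). Pcdhb9 rose from 14.3 ± 1.26 to 22.4 ± 2.30 CPM (0.65, SE 0.08), and Pcdhb5 from 4.73 ± 0.592 to 8.36 ± 1.07 CPM (0.83, SE 0.13). Pcdhb3 rose from 6.54 ± 0.961 to 11.4 ± 1.11 CPM (0.81, SE 0.15) and Pcdhb2 from 3.61 ± 0.501 to 6.11 ± 0.823 CPM (0.77, SE 0.14). C4b rose from 30.9 ± 6.15 to 90.8 ± 41.7 CPM (1.55, SE 0.27, adjusted p = 0.0146), and the lysosomal protease gene Ctss from 68.7 ± 6.41 to 99.6 ± 16.7 CPM (0.54, SE 0.10). H2-D1 rose from 29.8 ± 3.20 to 46.9 ± 4.29 CPM (0.65, SE 0.11) and H2-T23, a further class I gene, from 5.28 ± 0.412 to 8.47 ± 1.04 CPM (0.68, SE 0.15). The transcription factor gene Jund rose from 45.2 ± 2.39 to 65.4 ± 4.81 CPM (0.53, SE 0.07, adjusted p = 0.000525) and the phosphatase gene Dusp1 from 11.3 ± 1.46 to 16.8 ± 2.16 CPM (0.57, SE 0.11). The largest rises by the fixed rule were those of the secreted protease gene Klk6 (1.74, SE 0.37), C4b, Scand1 (1.34, SE 0.20), Mypn (1.19, SE 0.26) and Gpr84, a receptor of medium-chain fatty acids (1.12, SE 0.23).

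Of the 8 genes that fell in treadmill mice, 1 was in the cell cycle list and 2 were in the oligodendrocyte precursor list, which as a list was not called (adjusted p = 0.0829). Top2a, the topoisomerase of dividing cells, fell from 1.51 ± 0.277 to 0.564 ± 0.139 CPM (-1.43, SE 0.24, adjusted p = 0.00555). Gpr17, a receptor of committed oligodendrocyte precursors, fell from 55.7 ± 5.76 to 29.5 ± 8.54 CPM (-0.92, SE 0.16, adjusted p = 0.0130), and Neu4, a sialidase, from 12.2 ± 0.951 to 9.45 ± 1.01 CPM (-0.37, SE 0.08, adjusted p = 0.0429). Mid1 (-0.81, SE 0.16), the neuronal transcription factor gene Nhlh2 (-0.78, SE 0.16) and Tsga10 (-0.38, SE 0.08) also fell. The cell cycle list was lower with 14 of 22 members negative and a median of -0.10 (adjusted p = 0.0119, and adjusted p = 0.132 with an estimated correlation). The proliferation marker Mki67 measured 1.53 ± 0.269 against 2.34 ± 0.396 CPM (-0.61, SE 0.20, adjusted p = 0.236). Adult neurogenesis genes were negative in 13 of 18 with a median of -0.15 (adjusted p = 0.0146, and adjusted p = 0.177 with an estimated correlation), whereas Dcx measured 24 ± 5.86 against 22.0 ± 1.55 CPM (0.13, SE 0.15, adjusted p = 0.787). Antigen presentation was higher with 11 of 19 members called when adjusted over the list alone (median 0.41, adjusted p = 1.22e-08, and adjusted p = 0.172 with an estimated correlation), as were interferon-stimulated genes, positive in 24 of 24 (median 0.39, adjusted p = 5.80e-07, and adjusted p = 0.323 with an estimated correlation). Dentate granule neuron markers were negative in 11 of 11 with a median of -0.34 (adjusted p = 0.000116, and adjusted p = 0.328 with an estimated correlation). In the same mice the mean score moved from -0.11 to 0.161 for neocortex and from -0.175 to 0.116 for striatum. It moved from -0.072 to 0.127 for CA1, from 0.12 to -0.143 for CA2 and CA3, and little, from -0.014 to 0.032, for thalamus. Whether the dissected regions differed between ages was not tested. All 18 choroid plexus markers were negative with a median of -1.04 (adjusted p = 0.00238, and adjusted p = 0.650 with an estimated correlation), with 2 libraries high in these markers at 5 months and 1 at 20 months. In the remaining treadmill libraries the choroid plexus scores ran from -1.14 to -0.433 at 5 months and from -2.07 to -1.30 at 20 months. Without the 5 libraries high in these markers 32 genes were called, 22 of them among the 65, and without replicate 1 of the 5-month treadmill group 29.

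**Figure D4:**
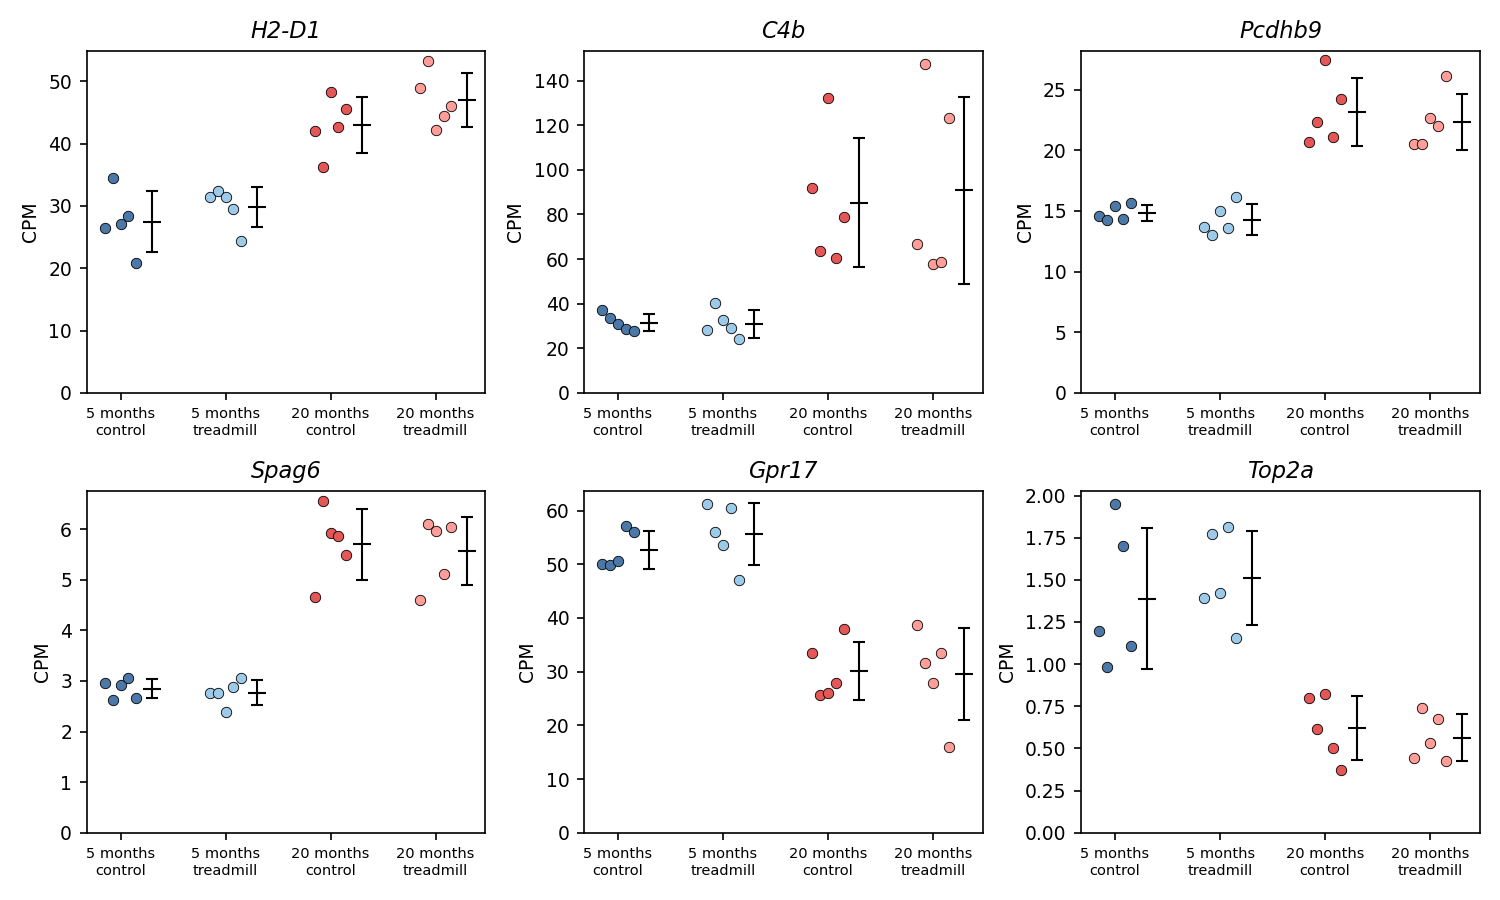
Normalised expression (CPM, y axis from 0) of 6 genes in each library of the 4 groups (x axis); points are libraries, and bars are the group mean and SD (n = 5). Spag6 rose in controls from 2.85 to 5.69 CPM, and Gpr17 fell in treadmill mice from 55.7 to 29.5 CPM.

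Of the 12 genes higher with age in controls, 11 were also called higher in treadmill mice, where 0.0404 were given by independent lists, and all 12 had a positive change there. The 2 comparisons shared no library. The interaction, which tests the difference of the age change between treadmill and control mice, called 0 genes. Whether treadmill exercise at 20 months moved age-related genes back was read from the 12 genes called in controls. In 8 of the 12, or 66.7%, the treadmill change at 20 months went against the age change. Both comparisons used the 20-month controls, and groups simulated without any treadmill or age change against such shared controls gave 92.3% (SD 7.92, 100 simulations). Genes selected there rested on spread alone, whereas 11 of the 12 real genes were also called in treadmill mice. The simulated share is therefore no reference for the 66.7%. With the controls divided so that no library served both changes, the share of the 12 genes averaged 56.3% over 20 divisions, from 33.3% to 75.0%. The 12 genes had still been selected with all 20-month controls, each as higher there. A pull against the age change therefore remained, and the share cannot tell whether the treadmill moved these genes back. Over all 16945 genes the covariance of the age and treadmill changes was -0.00692, against -0.0201 in the simulation, and 0.0109 with divided controls. The simulation held no shared differences between libraries, so its covariance is no reference either. Replicate 1 of the 20-month controls, high in choroid plexus markers, fell into only 1 part of each division. Its effect on the 0.0109 was not tested. With 1 library left out the covariance with undivided controls ran from -0.0145, without that replicate, to -0.00502, without replicate 2 of the 5-month controls.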

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

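Chosen only after the result was seen were the removal of the 5 libraries high in choroid plexus markers, both tests of the ependymal list, both tests of the choroid plexus markers and the splits for the average age effect. The criteria for a larger age change in treadmill mice and for the ependymal explanations were changed after their values were seen. In tests of the most extreme library of each group over scores, library measures and panel genes, 31 values stood apart, where chance gives 12.6, about 1 in 20 tests.

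Age called 65 genes in treadmill mice and 12 in controls. The called genes of treadmill mice had a median transcript GC content of 53.9% against 50.0% over all genes, but with GC offsets the counts were still 62 and 13, and without the 5 libraries high in choroid plexus markers 32 and 8, which argues against either as the whole source of the gap. Whether the age change itself was larger in treadmill mice cannot be told apart from chance: 61 of the 65 genes had a larger change there (median 0.765 against 0.431 in controls), yet 0 were called for the interaction when adjusted over the 65 (smallest adjusted p = 0.104, edgeR). A count of 0 had been set beforehand as evidence against a larger change, which was wrong, since the median half-width of the interaction's 95% interval, 0.406, exceeded the median interaction, 0.275. These 65 genes were also selected for their change in treadmill mice, which by itself favours a larger value there.

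The ependymal list was lower in treadmill mice at 20 months, with a median of -0.577 and a score difference within the spread of the libraries (two-sided exact permutation p = 0.159). With the choroid plexus score as a covariate the median was -0.442. The 5 libraries high in choroid plexus markers dominate that score. The fit therefore cannot tell how far less ventricular tissue in the sample accounts for the lower list. At 5 months the score difference was -0.09 (two-sided exact permutation p = 0.802), which neither shows nor excludes a treadmill effect at both ages. As the pattern itself was not larger than the spread, these explanations cannot be told apart.

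Choroid plexus markers were high in 5 libraries. Of the 18 markers, 17 were at least 4 times the median of the other 15 libraries in each of the 5, and Slc29a4 was not. The same 18 markers had defined the 5 libraries, by a score above 2, so this count was largely fixed by that choice. A candidate explanation is choroid plexus tissue carried along in the dissection, since Ttr reached 3198 to 6826 CPM. The groups held 1, 2, 1 and 1 of these libraries (Fisher's exact p = 1), which argues against the treadmill or the age as the source of these 5. It does not cover the other 15 libraries, whose scores ran from -1.17 to -0.249 at 5 months and from -2.07 to -1.30 at 20 months. Among those the markers were thus lower at 20 months, and the cause was not tested. The same tissue was not weighed for the libraries' other scores.

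Splits of the same libraries numbered 60 per comparison with the real one included. Past the adjusted threshold, the real split gave 12 genes for age in controls (highest other split 1) and 65 in treadmill mice (highest other 11). For the average age effect it gave 320 (highest other 1). In each, 1 of 60 gave as many genes, the smallest share 60 splits can give, so chance is made unlikely rather than excluded. The spread was estimated anew in each split, and splits that mix the ages put any age difference into it. By the count at an unadjusted p under 0.05 the real split stood alone only for the average age effect (3019 genes, 1 of 60, highest other 2435). Here 13 of 60 splits gave as many as the 1293 in controls (highest other 3110) and 4 of 60 as many as the 2113 in treadmill mice (highest other 2454). For the treadmill contrasts the real count was 0, so 60 of 60 splits gave as many by construction, which tests nothing. At that unadjusted p, where the real counts were 295 at 5 months, 309 at 20 months, 328 for the interaction and 274 for the average, 54, 52, 50 and 53 of the 60 splits gave as many, so chance was not excluded. The highest other splits called 0, 1, 57 and 508 genes after adjustment, and the 57 and 508 point to a structure of the samples whose source was not tested.

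Replicate 1 of the 5-month controls stood apart in many measures. Its scores were 0.130 for neurotrophic and exercise-linked factors, 0.132 for homeostatic microglia, 0.0869 for disease-associated microglia, 3.53 for choroid plexus, 0.294 for mitochondrial-encoded genes, 0.283 for ribosomal proteins, -0.426 for beta protocadherins and 0.122 for antioxidant genes. Mitochondrial genes held 6.22% of its counts and its 10 largest genes 7.06%, Gfap measured 530.2 CPM and Ttr 4988 CPM. Replicate 1 of the 20-month controls had scores of 0.233 for adult neurogenesis, 3.68 for choroid plexus and 1.24 for the ependymal list, with Ttr at 5562 CPM. Replicate 1 of the 20-month treadmill group had scores of 0.101 for oligodendrocyte precursors, 3.64 for choroid plexus and 0.276 for thalamus, with Ttr at 5299 CPM.

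Further libraries apart from their groups were these. The neocortex score was -0.256 in replicate 3 of the 5-month treadmill group. The histone score was 0.932 in replicate 2 of the 5-month and 0.286 in replicate 2 of the 20-month treadmill group. The glucocorticoid-responsive score was 0.239 in replicate 2 of the 5-month controls and 0.267 in replicate 3 of the 20-month controls. The unfolded protein and integrated stress response score was 0.279 in replicate 5 of the 5-month controls and -0.0808 in replicate 2 of the 5-month treadmill group, where Fkbp5 measured 56.5 CPM. In replicate 5 of the 20-month treadmill group mitochondrial genes held 5.95% of counts and the 10 largest genes 6.61%. Bdnf measured 61.2 CPM in replicate 5 of the 5-month treadmill group.

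The treadmill differences of 2 scores differed between ages before adjustment. For lymphocytes the difference at 20 months minus that at 5 months was -0.878 (two-sided exact permutation p = 0.00945, adjusted p = 0.387), and for CA2 and CA3 pyramidal neurons -0.217 (p = 0.0363 by the same exact test, adjusted p = 0.745).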

How the results depend on the processing

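Of the alternatives, the removal of the 5 libraries high in choroid plexus markers, the GC offsets, the average age effect and the agreement of the age changes were chosen after seeing the data. The 4 treadmill contrasts called 0 genes under every setting run, each left-out library included. Age in control mice, 12 genes, gave 44 with DESeq2, 1 with limma on the deposited RPKM, 4 with only the libraries compared and 9 to 16 with 1 library left out. Age in treadmill mice, 65 genes, gave 187 with DESeq2, 2 on RPKM, 32 without the 5 libraries and 29 (without replicate 1 of the 5-month treadmill group) to 82 with 1 left out. The counts without replicates 3, 4 and 5 of that group were 36, 34 and 39, and without replicates 1 and 5 of the 20-month treadmill group 42 and 33. The average age effect, 320 genes, gave 657 with DESeq2, 27 on RPKM, 147 without the 5 libraries and 154 to 472 with 1 left out. The RPKM columns kept their depth, which moved the median of all genes by up to 0.31 on the log2 scale for age in controls and -0.32 for the interaction; on RPKM Creb1, Itm2a and Chordc1 turned to 0.06, 0.059 and 0.053 for the average age effect. The cause of these differences was not tested. Of 9 named genes called for age in controls, AC149090.1 included, 1, 3 and 5 were called on RPKM, with only the libraries compared and without the 5 libraries; of 21 in treadmill mice, again with AC149090.1, 1, 13 and 8. The 1 called on RPKM was AC149090.1 in both, so every other named gene lost its call there. None of these 9 and 21 changed sign under any setting run.

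Lists called by camera depended on the correlation. With an estimated correlation 1, 0, 0, 0, 7, 1 and 5 lists were called for treadmill at 5 months, at 20 months, the interaction, the average treadmill effect, age in controls, age in treadmill mice and the average age effect. With fry's direction p they were 0, 0, 0, 0, 7, 5 and 10, and with its mixed p 0, 0, 0, 0, 7 and 11 for the first 6. At 5 months 12 lists were called with the choroid plexus covariate, and at 20 months 9 without the 5 libraries. With 1 library left out the counts ran from 7 to 20, from 6 to 22, from 12 to 25 and from 9 to 22 for the 4 treadmill contrasts. The correlation of the treadmill changes, -0.0893, ran from -0.190 to 0.0401 with 1 library left out and was positive without replicate 3 of the 20-month treadmill group (0.0130) or replicate 1 of the 20-month controls (0.0401). The correlation of the age changes, 0.449, was 0.318 without the 5 libraries, now past the threshold, and ran from 0.255 to 0.515 with 1 left out; the cause was not tested. Of 14446 genes with a mean of at least 1 CPM, 77.5% had a 95% interval of the interaction within 1.5-fold either way. No paired analysis was possible because no number is shared between groups in the labels.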

Other observations

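The average age effect over both treadmill groups, 10 libraries of 20 months against 10 of 5 months, was added after seeing the data. It called 320 genes, 234 higher and 86 lower, in edgeR's test. By exact permutation of the list scores, 12 of 41 lists passed the threshold after adjustment (smallest adjusted p = 0.00129). Complement genes were positive in 12 of 15 with a median of 0.36, 5 of them called higher, but the list lost its call with an estimated correlation (adjusted p = 5.33e-07, and adjusted p = 0.0969 with it). C4b rose from 31.2 ± 4.82 to 88.1 ± 34.03 CPM (SD, n = 10 each; log2 fold change 1.49, SE 0.19, adjusted p = 0.000434), and C1qa, C1qb and C1qc, the subunits of C1q, by 0.44, 0.37 and 0.36. Clec7a, a receptor of phagocytes, rose by 1.91 (SE 0.31), Itgax by 1.55 (SE 0.32) and Trem2 by 0.39 (SE 0.08). Of the homeostatic microglia genes, 15 of 16 were positive, with Ctss (0.49, SE 0.07) and Laptm5 (0.23, SE 0.05) called higher and Fcrls called lower (-0.55, SE 0.14); this list too lost its call with an estimated correlation (adjusted p = 1.41e-06, and adjusted p = 0.276 with it). Markers of disease-associated microglia were positive in 18 of 20 members, 6 of them called higher (adjusted p = 3.00e-11, and adjusted p = 0.0482 with an estimated correlation). Antigen presentation genes were positive in 18 of 19, 6 of them called, among them H2-K1 (0.60, SE 0.10) and B2m, the light chain of class I (0.40, SE 0.07; adjusted p = 1.23e-16 for the list, and adjusted p = 0.0249 with an estimated correlation). Beta protocadherins were positive in 21 of 22, 10 of them called (adjusted p = 4.52e-23, and adjusted p = 0.0152 with an estimated correlation).

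Some genes of dividing cells and young neurons were lower. Top2a fell from 1.45 ± 0.340 to 0.592 ± 0.161 CPM (-1.29, SE 0.17, adjusted p = 0.000204), Cenpf by -0.90 (SE 0.18) and the mitotic kinesin gene Kif11 by -0.55 (SE 0.12) on the log2 scale, and the cell cycle and adult neurogenesis lists kept their calls with an estimated correlation (adjusted p = 0.0249 each). Draxin, an axon guidance gene, fell (-1.09, SE 0.18), as did Sox11, a transcription factor of immature neurons (-0.36, SE 0.09), but Dcx was not called (22.5 ± 4.78 against 23.2 ± 3.51 CPM; -0.04, SE 0.11, adjusted p = 0.886). Gpr17 fell from 54.2 ± 4.77 to 29.8 ± 6.73 CPM (-0.86, SE 0.12). The clock genes Dbp, Cry2 and Bhlhe41 rose by 0.45, 0.15 and 0.30, but the circadian list lost its call with an estimated correlation (adjusted p = 0.00173, and adjusted p = 0.256 with it). Creb1 fell (-0.21, SE 0.04), a sign that turned on the deposited RPKM values. Across the 16945 genes, the age changes of control and treadmill mice, which share no library, had a Pearson correlation of 0.449 and a Spearman correlation of 0.429 (exact permutation p = 0.0776 and p = 0.00857 over 63504 assignments). Genes are not independent replicates.

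Some genes outside the naming rule were named as well, singled out after their values were seen. AC149090.1, on an unplaced scaffold at 52190 to 59690, rose with age from 48.7 ± 11.6 to 160.9 ± 34.6 CPM in controls (1.72, SE 0.18, adjusted p = 9.48e-05) and from 43.8 ± 4.91 to 172.5 ± 36.3 CPM in treadmill mice (1.98, SE 0.18), and was called in each of the 31 alternatives run for either comparison. Pisd-ps1 rose as well (0.82, SE 0.12 in controls), while its relatives Pisd (0.01, SE 0.05) and Pisd-ps2 (-0.03, SE 0.16) did not pass the threshold. Spag6, called in controls, has a near copy, Spag6l, that did not pass it (0.04, SE 0.19). E230020A03Rik, Gm38340 and Gm37827, neighbours on chromosome 7, rose in treadmill mice by 2.12, 1.54 and 2.26. How reads were divided among similar or overlapping genes is not given in the sources used here.

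The ratio of count to deposited RPKM cycled along the gene rows with a period of 40. The residual SD of its log2 was 0.0478 at that period, 0.192 at a period of 20, the number of libraries, and 0.333 around the gene mean alone.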
